A study of Mus musculus with 5 samples.

How the data were processed

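Poly(A)-selected RNA was measured by sequencing in 4 brain regions that had been microdissected from adult male wild-type C57BL/6 mice and snap-frozen. The subventricular zone (SVZ), the olfactory bulb (OB) and the dentate gyrus (DG) are the 3 neurogenic regions of the design, and the striatum (STR) is its non-neurogenic control tissue. The SVZ had 2 samples, which the labels call biological replicates, and OB, DG and STR had 1 sample each. RNA was extracted with Trizol and cleaned on RNeasy columns with DNase, and libraries followed standard Illumina protocols, per the labels' protocols. The design text mentions both paired-end and single reads without saying which sample had which, and the strandedness of the libraries is not given in the sources used here. Reads of overlapping genes on opposite strands, such as Dlx1 and its antisense neighbour Dlx1as, can therefore not be told apart.

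CASAVA, TopHat 1.2.0, Cufflinks 1.0.0 and the mouse genome build mm9 are named in the submitters' processing notes, which give no role or order. The deposited expression table holds FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) that the authors computed for 37142 transcripts in the 5 libraries. Of these, 8992 were transcripts of the authors' long noncoding RNA (lncRNA) catalogue and 28150 were RefSeq transcripts, 25975 of them coding by accession and 2175 noncoding. The second deposited file gives the exon structure of the 8992 catalogue transcripts on mm9. FPKM values carry no read counts. The low values were not whole multiples of 1 step per library. With a tolerance of 0.1 step, 23.9% to 34.4% of them lay near a whole multiple of the best-fitting step. Chance gives 20% for a step fixed in advance, and more for a step chosen from the same values. The sequencing depth is therefore unknown, and no counting interval is given. A value of 0 can be a failed estimate, and such genes are described as listed at 0.

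Values of transcripts with the same symbol were summed, which gave 20340 coding genes and 1719 RefSeq noncoding genes. Catalogue transcripts were summed over the authors' gene identifier to 5732 lncRNA loci, and those of a named lncRNA were joined with its RefSeq transcripts at the same deposited locus. Coordinates are those of the deposited files on mm9, counted from 1. The reference sequences used here were GENCODE M21, which is on another build, so no coordinate was taken from them. They served for the strand of symbols, the GC content of transcripts and the sequences of processed pseudogenes.

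Each of the 6 pairs of regions was compared on log2(FPKM + 1), so that folds of low genes are understated. limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) was fitted to all 5 libraries with 4 region groups. Its only residual degree of freedom came from the SVZ pair, so the standard errors of OB, DG and STR assume that those regions vary like the SVZ samples. P-values were adjusted by the Benjamini-Hochberg method over the genes at 1 FPKM or more in a library of either region. No gene had an adjusted p under 0.05 in any pair, so genes were counted by size: those with a log2 difference of 2 or more, a 4-fold difference on this scale, among genes at 1 FPKM or more in either region. Region-enriched genes were at least 2 log2 units above, or below, each of the other 3 regions. The genes named in the text were the 10 coding genes with the largest difference each way among those at 5 FPKM or more, and the 5 lncRNA loci each way at 1 FPKM or more, with the same direction in both SVZ samples. The rule also took list members: the first 4 detected, those with the largest difference each way, and all named lncRNAs. As written the rule asked for a passed test, and it was applied without it. Other members of the lists are named as examples and were chosen after their values were seen.

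The lists, 21 in number, covered neural stem cells and astrocytes, transit-amplifying and cycling cells, migrating neuroblasts, ependymal cells, choroid plexus, striatal projection neurons, dentate granule neurons, cortical and CA (hippocampal Ammon's horn) excitatory neurons, olfactory bulb neurons, olfactory ensheathing glia and olfactory nerve, GABAergic neurons, oligodendrocytes, oligodendrocyte precursors, endothelial and mural cells, microglia, meningeal fibroblasts, blood, immediate early genes, cytosolic ribosomal proteins, reference genes and named lncRNAs. Hba-a1, Hbb-b2 and Pantr1 were not found in the table under those symbols. The groups, comparisons, lists, naming rule and most alternative settings were fixed before the data were examined. For each list and pair, the median log2 difference over members at 1 FPKM or more in any region is given relative to the median of all coding genes, and members are counted as higher or lower when they differ by at least 1 log2 unit before that subtraction. Its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression, describes these libraries, and the central range runs from the 2.5th to the 97.5th percentile. Some members count in their lists and are not reported singly here. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the 126 combinations of list and pair, and again with the correlation estimated from the data. That estimate rests on the only residual degree of freedom, from the SVZ pair, so it cannot decide whether a list call holds. The limma p-values of list members were also adjusted over the list alone.

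The 5 libraries fell into 2 library sets that the labels do not name, SVZ sample 1 with OB and DG, and SVZ sample 2 with STR. Differences between SVZ and STR were therefore also taken from SVZ sample 2 alone, and those between SVZ and OB or DG from SVZ sample 1 alone. Differences of OB and DG from STR were also bridged, that is, the STR value of each gene was shifted by the difference of SVZ sample 1 from SVZ sample 2. This step was chosen after seeing the data. The other alternatives were pseudocounts of 0.1 and 5, rescaling by median ratio and by the upper quartile, no minimum or a minimum of 5 FPKM, a difference of 1 instead of 2, the transcript with the highest mean in place of the sum, each SVZ sample left out, transcripts of 200 bases or more, and genes less than 1 log2 unit apart between the SVZ samples. Processed pseudogene copies were alignments by BLAST+ 2.17.0 with at least 90% identity over at least 300 bases.

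The tests were tested on simulated data made from the real levels, with 200 genes changed. In SVZ against STR (14980 to 15045 genes) limma called 0 of the 200 at changes of 2 and of 3 log2 units and 189 at 6, and the size threshold found 50.5%, 94.5% and 100%, with 1.12% to 1.29% of unchanged genes beyond it. In OB against STR (14990 to 15006 genes) limma called 0, 0 and 178, and the size threshold found 52.5%, 92% and 100%, with 2.18% to 2.24% of unchanged genes beyond it. Of 50 random lists of 15 genes, 6% lay outside the 2.5th to 97.5th percentiles with no shift and 94% with a shift of 1 (OB against STR, 15692 genes). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.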

Results

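The 5 libraries covered the 3 neurogenic regions of the adult mouse brain and the striatum, with 2 biological replicates of the SVZ and 1 sample each of OB, DG and STR. Coding genes at 1 FPKM or more numbered 13014 in the SVZ mean, 13072 in OB, 12460 in DG and 12275 in STR, of 20340 in the table. The read depth of the libraries is unknown, because FPKM values carry no counts. The DG library stood apart in its low values: 16725 of its transcripts were listed at 0, against 9564 to 10807 in the other 4 libraries, and the 5th percentile of its values above 0 was 0.122 FPKM, against 0.0167 to 0.0292. Since OB, DG and STR had 1 sample each, the error of every difference below rests on the spread between the 2 SVZ samples. Errors are limma standard errors on the log2(FPKM + 1) scale (SE, n = 2 SVZ samples and 1 sample of each other region).

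Across 14029 coding genes, SVZ sample 2 correlated more with STR (Pearson r = 0.968) than with SVZ sample 1 (r = 0.943), while SVZ sample 1 and STR gave r = 0.912. Genes are not independent replicates, so these values describe the libraries. RefSeq transcripts shorter than 200 bases were at 1 FPKM or more 153 times in SVZ sample 2 and 161 times in STR, and 24, 19 and 14 times in SVZ sample 1, OB and DG. Gapdh, the glycolytic reference gene, was listed at 32.4 and 39.5 FPKM in SVZ sample 2 and STR and at 457, 563 and 414 FPKM in SVZ sample 1, OB and DG. It has 167 processed pseudogene copies in the reference. These 2 library sets cut across the regions, so values within a set are given beside the pooled ones. Libraries of 1 set were not free of such differences. The log2 difference followed the GC content of coding genes for OB minus DG (Spearman rho = 0.240) and SVZ sample 1 minus OB (-0.275). For SVZ sample 1 minus DG rho was 0.004, and for SVZ sample 1 minus SVZ sample 2, across the sets, 0.703.

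**Figure D1:**
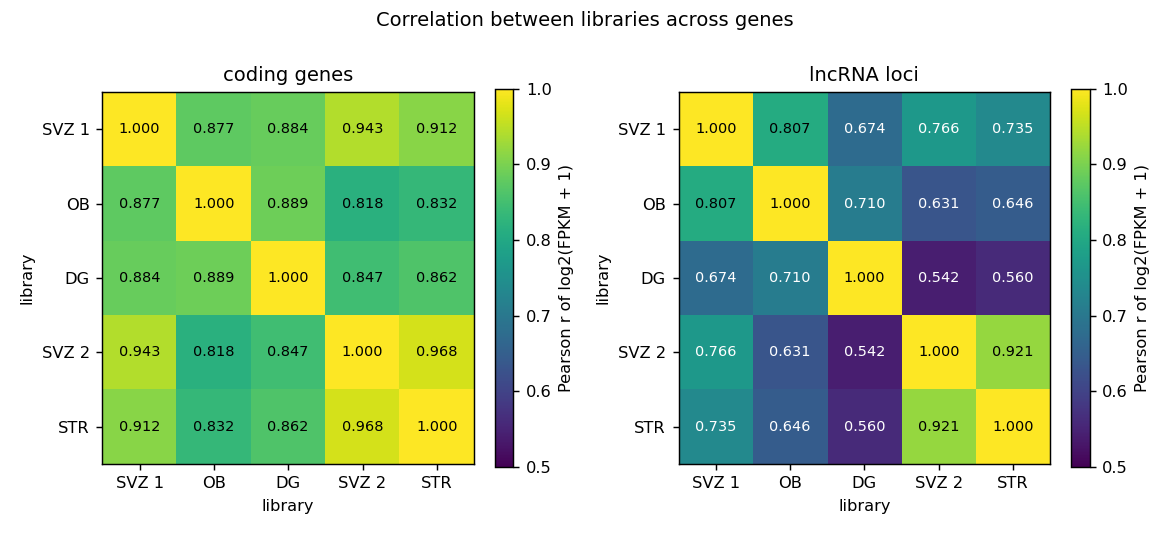
Pearson correlation of log2(FPKM + 1) between each pair of the 5 libraries, over 14029 coding genes and over 1862 lncRNA loci. SVZ sample 2 and STR had the highest r in both panels, 0.968 for coding genes and 0.921 for lncRNA loci.

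The SVZ was compared with the striatum, its neighbour without neurogenesis, and the largest differences were in genes of the cell types of the ventricle wall. Ependymal genes, which build the motile cilia of the ventricle wall, stood farthest apart: all 15 were at least 1 log2 unit higher in the SVZ, with a median of 3.51 above that of all coding genes. Ccdc153, at chromosome 9, 44048760 to 44055389, was at 55.0 and 23.9 FPKM in the SVZ samples and 0.0927 in STR, a log2 difference of 5.10 ± 0.67. Foxj1, the master transcription factor of motile cilia, was at 61.0 and 23.5 FPKM against 1.95 (3.72 ± 0.74), and Ak7, an adenylate kinase of cilia, was 4.30 ± 0.48 higher. Tmem212 was at 47.9 and 16.6 FPKM and was listed at 0 in STR. By limma, 14 of the 15 ependymal genes had p under 0.05 adjusted over the list alone, all of them higher in the SVZ. Tekt4 was the exception, with a difference of 1.59 ± 0.54.

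Transit-amplifying and cycling cell genes were at least 1 unit higher in the SVZ for 15 of 16 members, with a relative median of 1.88, and 10 of the 16 passed limma adjusted over the list alone. The proliferation antigen Mki67 was 2.92 ± 0.42 higher, topoisomerase Top2a 3.86 ± 0.42 and the ribonucleotide reductase subunit Rrm2 3.15 ± 0.38. Pcna, the polymerase clamp, was not separated from its error (0.25 ± 0.62). Migrating neuroblast genes were at least 1 unit higher for 12 of 16 members and lower for 0, with a relative median of 1.92, and 9 passed adjusted over the list alone. Doublecortin (Dcx), a microtubule protein of migrating neurons, was at 16.3 and 18 FPKM against 2.54 (2.36 ± 0.40). The interneuron homeobox gene Dlx1 was 3.77 ± 0.44 higher and the surface protein gene Cd24a 3.87 ± 0.38, while Robo2 gave -0.62 ± 0.40.

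Neural stem cell and astrocyte genes had a relative median of 0.89, with 7 of 14 at least 1 unit higher. Thbs4, an extracellular matrix protein of SVZ astrocytes at chromosome 13, 93521541 to 93564773, was at 70.5 and 27.7 FPKM against 1.24 (4.34 ± 0.73). The intermediate filament genes Vim and Gfap were 3.06 ± 0.67 and 1.57 ± 0.66 higher, and the general astrocyte genes Slc1a3 and Aqp4 gave 0.37 ± 0.47 and 0.12 ± 0.38. By limma 0 of these 14 genes passed adjusted over the list alone, and 3 had an unadjusted p under 0.05. Choroid plexus genes, which include the thyroxine carrier Ttr (15.1 and 18.2 against 6.37 FPKM), had a relative median of 0.64 (4 of 9 higher, 0 of 7 tested passing). Immediate early genes, which respond to neuronal activity and to handling of tissue, had a relative median of 1.11, with 7 of 10 higher, among them Fos at 2.25 ± 0.48, and 0 passed adjusted over the list alone.

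Striatal projection neuron genes lay near the striatal level in both SVZ samples, with a relative median of -0.33 and 1 of 18 members at least 1 unit apart. The dopamine receptor gene Drd1a was at 108 and 119 FPKM against 158 in STR (-0.47 ± 0.39), and the opioid precursor Penk was at 1581 and 1684 against 1213 FPKM. Prodynorphin (Pdyn) was the member that stood apart, at 133 and 116 against 31.2 FPKM (1.96 ± 0.39). Among the genes lower in the SVZ were the cannabinoid receptor Cnr1, at 21.7 and 35.2 against 162 FPKM (-2.51 ± 0.50), the retinaldehyde dehydrogenase Aldh1a1 (-2.50 ± 0.43), the orphan receptor Gpr139 (-2.64 ± 0.32) and the vesicular glutamate transporter Slc17a7 (-2.22 ± 0.65). Cortical and CA excitatory neuron genes had a relative median of -0.54, with 3 of 13 lower and 1 higher, and 0 of 12 tested passed.

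Over all 15012 genes tested, limma called 0 between SVZ and STR, with 566 higher and 151 lower at unadjusted p under 0.05 and a smallest adjusted p of 0.633. By size, 198 coding genes were at least 2 log2 units higher and 19 lower of 13187, and 10 and 18 of 1356 lncRNA loci. In the simulated data for this pair 1.12% to 1.29% of unchanged genes lay beyond the same threshold, so many of these genes may be noise. The lncRNA counts were 33 and 61 with SVZ sample 1 alone and 5 and 6 with SVZ sample 2 alone. Against SVZ sample 1 alone, which lies in the other set, the coding counts were 360 and 77. Within the set of SVZ sample 2 and STR they were 125 and 10, and the relative medians were 3.01 for ependymal, 1.64 for cycling, 1.81 for neuroblast, 0.70 for stem cell and astrocyte, 0.89 for immediate early and 0.66 for choroid plexus genes. Camera at the preset correlation called 7 lists: ependymal cells (adjusted p = 2.24e-20), cycling cells (1.44e-15), neuroblasts (1.69e-09), immediate early genes (4.5e-05), stem cells and astrocytes (5.93e-05), choroid plexus (0.00245) and, lower, cortical and CA neurons (0.0184). With an estimated correlation no list was called (adjusted p = 0.82 with an estimated correlation, and 0.866 for stem cells and astrocytes). That estimate rests on 1 residual degree of freedom and cannot decide whether the calls hold.

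**Figure D2:**
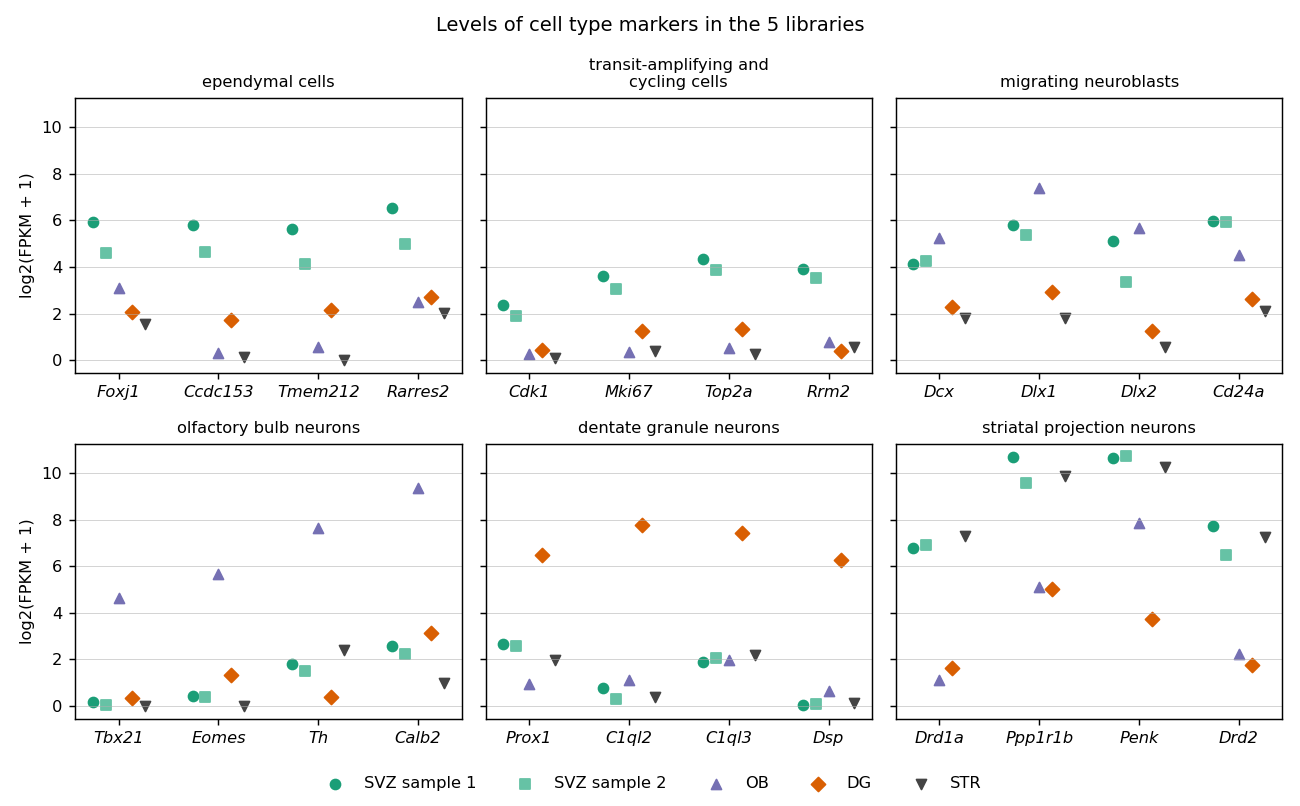
Levels, as log2(FPKM + 1), of 4 members of each of 6 cell type lists, with 1 point for each of the 5 libraries. Foxj1 and Top2a lie highest in the SVZ samples, Th in OB and Prox1 in DG, while Drd1a lies at 108 to 158 FPKM in STR and both SVZ samples and at 1.2 and 2.13 FPKM in OB and DG.

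The other lists were close to the coding median between SVZ and STR, with camera adjusted p from 0.0517 (striatal projection neurons) to 0.937 (oligodendrocyte precursors). The relative medians were -0.28 for microglia (0 of 10 members at least 1 unit apart), -0.22 for endothelial and mural cells (1 of 12 higher), -0.15 for oligodendrocytes (0 of 15) and 0.12 for oligodendrocyte precursors (0 of 6). They were -0.10 for GABAergic neurons (1 of 7 lower), -0.14 for dentate granule neurons (0 of 14), -0.18 for olfactory bulb neurons (2 of 15 higher) and -0.19 for olfactory ensheathing glia (1 of 7 higher). Meningeal fibroblast genes gave -0.19 (0 of 8), blood genes -0.25 (0 of 3), reference genes -0.21 (1 of 10 higher and 1 lower) and named lncRNAs 0.08 (1 of 16 higher and 1 lower). Cytosolic ribosomal protein genes gave -0.40 with both SVZ samples and 0.21 with SVZ sample 2 alone.

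Between the olfactory bulb, where SVZ-born neuroblasts end their migration, and the striatum, the largest differences were in genes of the bulb's own neurons and afferents. Olfactory bulb neuron genes were at least 1 unit higher in OB for 13 of 15 members (relative median 4.14), and 11 passed limma adjusted over the list alone. The calcium-binding protein gene Calb2, at chromosome 8, 112666438 to 112692106, was at 656 FPKM in OB and 0.981 in STR (8.37 ± 0.49). Tyrosine hydroxylase (Th), which marks periglomerular dopamine neurons, was at 200 against 4.24 FPKM (5.26 ± 0.48), and the mitral and tufted cell gene Cdhr1 was 6.70 ± 0.64 higher. The mitral cell transcription factors Eomes and Tbx21 were at 50.2 and 23.8 FPKM in OB and were listed at 0 in STR. S100a5, a calcium-binding protein of olfactory sensory neurons at chromosome 3, 90412444 to 90415702, was at 409 FPKM in OB and listed at 0 in every other library. Omp, the olfactory marker protein of the same neurons, was at 187 against 0.0852 FPKM (7.44 ± 0.40).

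Migrating neuroblast genes were higher in OB for 13 of 16 members (relative median 1.81), with 8 that passed adjusted over the list alone. Dlx1 was 5.59 ± 0.50, Sp8 5.51 ± 0.43 and Dcx 3.45 ± 0.46 higher. Olfactory ensheathing glia and nerve genes had a relative median of 2.67 (6 of 7 higher, 1 lower, 5 passing adjusted over the list alone), with Frzb, a secreted Wnt antagonist, at 55.3 against 0.575 FPKM. Meningeal fibroblast genes had a relative median of 2.40 (7 of 8 higher, all 7 passing), with Ptgds, the prostaglandin D synthase of the meninges, at 2178 against 226 FPKM. Stem cell and astrocyte genes had 0.73 (8 of 14 higher, 1 passing), led by the radial glia lipid-binding protein Fabp7, at 702 against 12.5 FPKM (5.70 ± 0.61). Immediate early genes gave 0.95 (7 of 10 higher, 0 passing).

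Striatal projection neuron genes were lower in OB for 17 of 18 members (relative median -4.51), and the same number passed limma adjusted over the list alone. The dopamine receptors Drd1a and Drd2 gave -6.17 ± 0.45 and -5.01 ± 0.80. Oligodendrocyte genes had a relative median of -1.45, with 6 of 15 lower and 2 higher, and 0 passed. The myelin genes Mobp and Mal gave -1.17 ± 0.56 and -1.96 ± 0.51, whereas the lineage factor genes Sox10 and Olig1 gave 1.35 ± 0.56 and 1.03 ± 0.70. Cytosolic ribosomal protein genes gave -1.14 (7 of 16 lower and 3 higher, 0 passing), and 0.06 once bridged through the SVZ.

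limma called 0 of 15248 genes between OB and STR, with 1541 higher and 607 lower at unadjusted p under 0.05 and a smallest adjusted p of 0.199. By size, 856 coding genes were higher and 268 lower of 13373, a share of 76.2% higher that became 51.2% (454 and 433) after median ratio scaling. In the simulated data for this pair 2.18% to 2.24% of unchanged genes lay beyond the threshold. The coding median itself differed by 0.49. Bridged through the SVZ the coding counts were 408 and 204, and the relative medians were 4.37 for bulb neurons, 1.48 for neuroblasts, 2.24 for ensheathing glia, 1.96 for meningeal fibroblasts, 0.57 for stem cells and astrocytes, 0.55 for immediate early genes, -1.25 for oligodendrocytes and -4.72 for striatal neurons. Camera called 9 lists at the preset correlation, with adjusted p of 1.26e-22 for striatal neurons, 6.63e-10 for bulb neurons, 2.64e-05 for neuroblasts, 0.000117 for meningeal fibroblasts, 0.000466 for oligodendrocytes, 0.00115 for ensheathing glia, 0.0234 for stem cells and astrocytes, 0.0277 for ribosomal proteins and 0.0476 for immediate early genes. With an estimated correlation, which cannot decide this at 1 residual degree of freedom, no list was called. The adjusted p was 0.82 with an estimated correlation, 0.889 for stem cells and astrocytes, and 0.866 for ribosomal and immediate early genes.

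In the dentate gyrus, the hippocampal niche, granule neuron genes were at least 1 unit higher than in the striatum for 13 of 14 members (relative median 3.99), and 12 passed limma adjusted over the list alone. The synaptic organiser C1ql2, at chromosome 1, 122237159 to 122239751, was at 217 against 0.322 FPKM (7.36 ± 0.48). Prox1, the homeobox gene that specifies granule cells, was at 89.5 against 2.94 FPKM (4.52 ± 0.46), and the desmosomal gene Dsp was 6.13 ± 0.34 higher. Calb1, the calcium-binding protein calbindin, was the member that did not stand apart, at 111 against 124 FPKM (-0.16 ± 0.50). It is a gene that striatal neurons also express. Among genes outside the list, the transcription factor Prdm8, at chromosome 5, 98609888 to 98616467, was at 146 against 0.350 FPKM (6.76 ± 0.38), and the metabotropic glutamate receptor Grm2 was at 118 against 0.312 FPKM. Cortical and CA excitatory neuron genes had a relative median of 3.03 (9 of 13 higher and 2 lower, 10 of 12 tested passing), with Neurod2 at 6.86 ± 0.55 and Slc17a7 at 752 against 21.4 FPKM. The lower members were Pou3f1 (-3.59 ± 0.46) and Wfs1 (-1.20 ± 0.66).

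Striatal projection neuron genes were lower in DG for 16 of 18 members (relative median -4.94), with 16 that passed adjusted over the list alone. Penk was at 12.4 against 1213 FPKM, and Bcl11b (-0.08 ± 0.46) and Pdyn (-0.49 ± 0.45) did not stand apart. Oligodendrocyte genes were lower by at least 1 unit for 10 of 15 members (relative median -1.83, 0 passing adjusted over the list alone), with the myelin gene Mal at 27.7 against 164 FPKM. GABAergic neuron genes had a relative median of -1.17 (3 of 7 lower, 0 of 6 tested passing), with the glutamate decarboxylase Gad2 at 22.3 against 125 FPKM (-2.43 ± 0.52). Meis2, a homeobox gene of striatal and bulb neurons, was at 1.35 against 135 FPKM (-5.86 ± 0.49). Markers of stem cells and astrocytes gave 0.57 (5 of 14 higher, 0 passing), with Gfap at 252 against 20.6 FPKM. Markers of meningeal fibroblasts gave 0.57 (3 of 8 higher, 1 of 7 tested passing), neuroblasts 0.27 (5 of 16 higher and 4 lower, 1 of 15 tested passing), ependymal cells 0.42 (5 of 15 higher, 0 of 10 tested passing) and cycling cells 0.11 (4 of 16 higher, 0 of 12 tested passing). Ribosomal protein genes gave -1.40 (8 of 16 lower and 2 higher, 0 passing), and 0.08 once bridged.

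limma called 0 of 14870 genes between DG and STR, with 937 higher and 827 lower at unadjusted p under 0.05 and a smallest adjusted p of 0.212. By size, 445 coding genes were higher and 317 lower of 13009, a share of 58.4% higher that became 44.8% (337 and 415) after median ratio scaling, and the coding median differed by 0.23. Bridged counts were 233 and 289, and the bridged relative medians were 4.23 for granule neurons, 4.19 for cortical and CA neurons, -4.78 for striatal neurons, -1.73 for oligodendrocytes, -0.90 for GABAergic neurons, 0.30 for stem cells and astrocytes, 0.52 for meningeal fibroblasts and -0.84 for named lncRNAs. Camera called 8 lists at the preset correlation, with adjusted p of 6.32e-19 for striatal neurons, 3.15e-13 for granule neurons, 1.4e-06 for oligodendrocytes, 0.00109 for cortical and CA neurons, 0.0188 for GABAergic neurons, 0.0309 for stem cells and astrocytes, 0.0454 for named lncRNAs and 0.0467 for meningeal fibroblasts. With an estimated correlation, which cannot decide this at 1 residual degree of freedom, no list was called. The adjusted p was 0.82 with an estimated correlation, and 0.889 for stem cells and astrocytes.

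**Figure D3:**
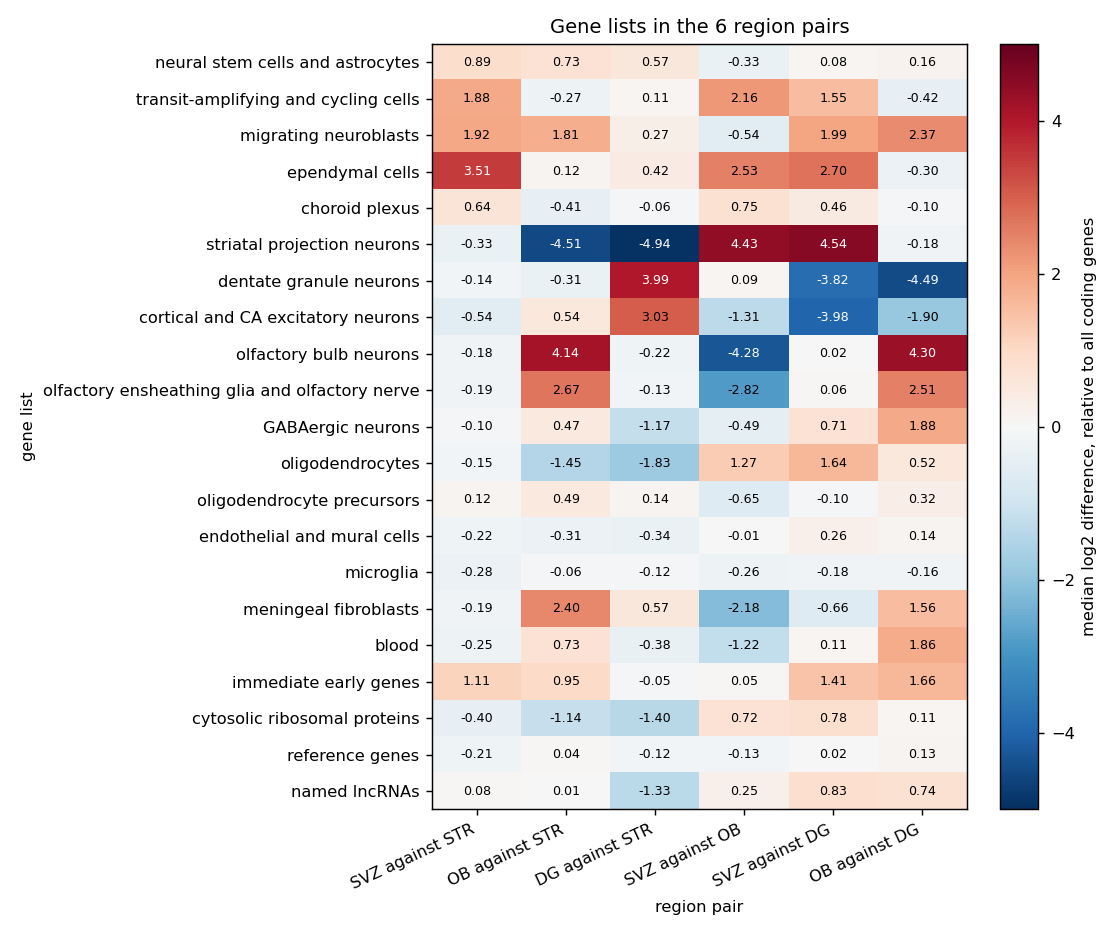
Median log2 difference of each of the 21 gene lists, relative to the median of all coding genes, in each of the 6 pairs of regions. Ependymal genes reach 3.51 in SVZ against STR, bulb neuron genes 4.14 in OB against STR and granule neuron genes 3.99 in DG against STR.

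Compared with the bulb, the SVZ was higher in ependymal genes (14 of 15, relative median 2.53, 11 passing adjusted over the list alone) and in cycling cell genes (13 of 16, 2.16, 9 passing), with Top2a at 19.3 and 13.8 against 0.439 FPKM. Neuroblast genes had a relative median of -0.54, with 8 of 16 lower and 2 higher, of which 1 passed, and camera did not call them (adjusted p = 0.211, and 0.889 with an estimated correlation). Dlx1 gave -1.81 ± 0.44 and Sp8 -3.18 ± 0.37, while Cd24a and Sox11, another neuroblast transcription factor, gave 1.46 ± 0.38 and 1.29 ± 0.42. Striatal genes were higher in the SVZ for 17 of 18 members (4.43, 17 passing). The homeobox gene Six3 was at 42.7 and 35.7 against 0.210 FPKM (5.05 ± 0.41). Bulb neuron genes were lower for 13 of 15 (-4.28, 12 passing), with Th at -6.00 ± 0.42. Meningeal fibroblast genes were lower for 7 of 8 (-2.18, 7 passing) and ensheathing glia genes for 5 of 7 (-2.82, 4 passing). Oligodendrocyte genes gave 1.27 (8 of 15 higher and 1 lower, 0 passing). Choroid plexus genes gave 0.75, with 3 of 9 higher and 2 lower (4 passing), the lower ones being the water channel Aqp1 (0.283 and 0.210 against 50.7 FPKM in OB) and the potassium channel Kcnj13. Aqp1 is also known in olfactory ensheathing glia.

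Between the SVZ and DG, which both hold dividing stem cells, the largest coding differences were in genes of the surrounding neurons. Granule neuron genes were lower in the SVZ for 13 of 14 members (relative median -3.82, 13 passing adjusted over the list alone) and cortical and CA neuron genes for 9 of 13, with 3 higher (-3.98, all 12 tested passing). C1ql2 gave -7.23 ± 0.42 and Neurod2 -7.38 ± 0.48. Striatal genes were higher for 17 of 18 (4.54, 17 passing), with Penk at 6.93 ± 0.56, and the neuropeptide gene Nts was at 46.4 and 39.3 FPKM in the SVZ and listed at 0 in DG. Among niche cells, ependymal genes were higher in the SVZ for 14 of 15 (2.70, 12 passing), cycling cell genes for 13 of 16 (1.55, 7 passing) and neuroblast genes for 9 of 16 (1.99, 7 passing). Mki67 was at 11.3 and 7.38 against 1.38 FPKM (2.09 ± 0.42) and Dcx at 16.3 and 18 against 3.90 FPKM (1.88 ± 0.40). Stem cell and astrocyte genes did not part the niches as a list (0.08, 5 of 14 higher and 1 lower, 0 passing), with Gfap at -1.97 ± 0.66 and Sox2 at 1.61 ± 0.38. Oligodendrocyte genes gave 1.64 (12 of 15 higher, 0 passing), immediate early genes 1.41 (9 of 10 higher, 3 passing) and meningeal genes -0.66 (3 of 8 lower, 1 of 7 tested passing).

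OB and DG, which lie in the same library set, were parted by granule neuron genes (13 of 14 lower in OB, relative median -4.49, 13 passing adjusted over the list alone) and bulb neuron genes (14 of 15 higher, 4.30, 13 passing). Prox1 gave -5.55 ± 0.46 and Th 7.26 ± 0.48. Neuroblast genes were higher in OB for 12 of 16 (2.37, 9 passing), with Sp8 at 45.4 against 0.171 FPKM. Ensheathing glia genes were higher for 7 of 7 (2.51, 5 passing), meningeal genes for 7 of 8 (1.56, 5 passing higher and 1 lower) and immediate early genes for 9 of 10 (1.66, 5 passing), with Egr1, an activity-dependent transcription factor, at 158 against 27.1 FPKM. GABAergic genes gave 1.88 (5 of 7 higher and 2 lower, 5 passing), with Sst at -2.37 ± 0.57. Cortical and CA genes gave -1.90 (8 of 13 lower and 3 higher, 7 of 12 tested passing) and blood genes 1.86 (2 of 3 higher, 1 passing).

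limma called 0 genes in each of these 3 pairs, of 15553, 15294 and 14997 tested. At unadjusted p under 0.05 there were 873 higher and 1331 lower for SVZ against OB (smallest adjusted p 0.137), 1274 and 894 for SVZ against DG (0.137) and 1295 and 596 for OB against DG (0.154). By size the coding counts were 286 higher and 496 lower for SVZ against OB, 394 and 289 for SVZ against DG and 492 and 195 for OB against DG. Median ratio scaling moved the share higher from 36.6% to 50.4% (346 and 341) for SVZ against OB and from 71.6% to 60.4% (368 and 241) for OB against DG. The coding medians differed by -0.24, 0.02 and 0.24. With SVZ sample 1 alone, in the set of OB and DG, the counts were 337 and 377 against OB and 465 and 237 against DG, and with SVZ sample 2 alone 309 and 768 against OB and 391 and 428 against DG. The relative medians of SVZ sample 1 against OB were 2.91 for ependymal, 2.13 for cycling, 4.62 for striatal, -4.38 for bulb neuron, -2.04 for meningeal, -1.74 for ensheathing glia, 1.10 for oligodendrocyte, 0.91 for choroid plexus and -0.46 for neuroblast genes. Against DG they were 3.30 for ependymal, 1.72 for cycling, 1.86 for neuroblast, -3.92 for granule neuron, -4.08 for cortical and CA, 4.49 for striatal, 1.5 for oligodendrocyte, 1.59 for immediate early and -0.66 for meningeal genes.

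Camera at the preset correlation called 8 lists for SVZ against OB, with adjusted p of 1.38e-20 for striatal neurons, 3.15e-13 for bulb neurons, 1.08e-11 for ependymal cells, 1.79e-11 for cycling cells, 4.79e-06 for meningeal fibroblasts, 0.00279 for oligodendrocytes, 0.00488 for ensheathing glia and 0.0475 for choroid plexus. It called 10 for SVZ against DG, with 6.19e-17 for granule neurons, 1.36e-16 for striatal neurons, 2.39e-09 for ependymal cells, 7.33e-08 for cycling cells, 1.22e-06 for neuroblasts, 1.15e-05 for oligodendrocytes, 4.37e-05 for cortical and CA neurons, 0.000229 for immediate early genes, 0.00587 for meningeal fibroblasts and 0.0234 for named lncRNAs. For OB against DG the 8 called lists were granule neurons (3.26e-23), bulb neurons (6.73e-17), neuroblasts (7.43e-07), cortical and CA neurons (3.79e-05), immediate early genes (3.95e-05), ensheathing glia (0.000296), meningeal fibroblasts (0.00488) and blood (0.0267). Over the 6 pairs camera called 50 of 126 combinations, and 0 with an estimated correlation (adjusted p = 0.82 with an estimated correlation for these 26 calls, except 0.866 for ependymal cells against DG and for blood). The estimate rests on 1 residual degree of freedom, so the 0 calls do not decide whether the lists differ. The medians of 64 of the 126 lay outside the central range of matched random lists.

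Genes enriched in 1 region over each of the other 3 numbered 84 in the SVZ, 237 in OB, 103 in DG and 14 in STR, of 13951 coding genes. After median ratio scaling these counts were 89, 157, 113 and 17, and after upper quartile scaling 90, 157, 109 and 16. As deposited, genes lowest in 1 region numbered 2, 34, 52 and 11. The SVZ set was led by cilia genes, Ak7 (3.66 above the next region), Ccdc153 (3.50) and Rsph4a (3.39). The OB set was led by S100a5 (8.68), Doc2g (7.22) and Omp (6.91), and the DG set by Prdm8 (6.76), C1ql2 (6.66) and Neurod2 (5.83). The STR set was led by Mtrnr2l (3.49) and the ribosomal protein genes Rps12 (2.90) and Rpl9 (2.77). Mtrnr2l and Rpl9 followed the library sets: Rpl9 was at 271 FPKM in SVZ sample 2 and 311 in STR, against 6.68, 3.41 and 6.03 in SVZ sample 1, OB and DG. Cnr1 (2.51) was at 162 FPKM in STR and 5.83 to 35.2 in the other libraries. With lncRNA loci included, the SVZ set held 88 genes, 47 with SVZ sample 2 alone and 147 with SVZ sample 1 alone, and the STR set held 29 genes, 6 and 109.

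The transcripts of the lncRNA catalogue fell into 5657 loci of overlapping transcripts on the same strand. Of the transcripts 4486 (49.9%) had 2 exons and 67 had 1. The median spliced length was 847 bases (quartiles 504 and 1780), against 2483 for coding RefSeq transcripts, and 560 transcripts were shorter than 200 bases. A deposited locus was shared with a coding transcript by 3127 (34.8%), and 2218 (24.7%) were listed at 0 in all 5 libraries. Of the 5732 lncRNA loci, 1196 were at 1 FPKM or more in the SVZ, 1003 in OB, 957 in DG and 1108 in STR. The median level of detected loci ran from 2.47 FPKM in the SVZ to 2.85 in DG, against 11.7 to 15.4 for coding genes.

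Loci enriched in 1 region made up 5.0% of detected lncRNA loci and 1.67% of coding genes in the same bins of highest value. In bins of the mean value the coding share was 3.49%. For transcripts of 200 bases or more the shares, in bins of highest value, were 3.11% and 1.63%. In the bin of 10 FPKM or more, 38 of 273 loci (13.9%) were enriched against 326 of 9290 coding genes (3.51%), and 19 of 239 (7.95%) for transcripts of 200 bases or more. By region 4 loci were highest in the SVZ, 19 in OB, 49 in DG and 15 in STR. With SVZ sample 2 alone 2 loci were highest in the SVZ and 3 in STR, and with SVZ sample 1 alone 13 and 50. Bridged through the SVZ, 4 were highest in STR. The 5 highest DG loci, led by XLOC_015077 (1552 FPKM, chromosome 3, 31290182 to 31335222), were each a single 2-exon model of 100 bases, listed at 0 in every other library. Loci with no transcript of 200 bases or more made up 25 of the 49 DG loci (51.0%) and 8 of the 15 STR loci (53.3%), against 109 of 1848 detected loci (5.90%).

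**Figure D4:**
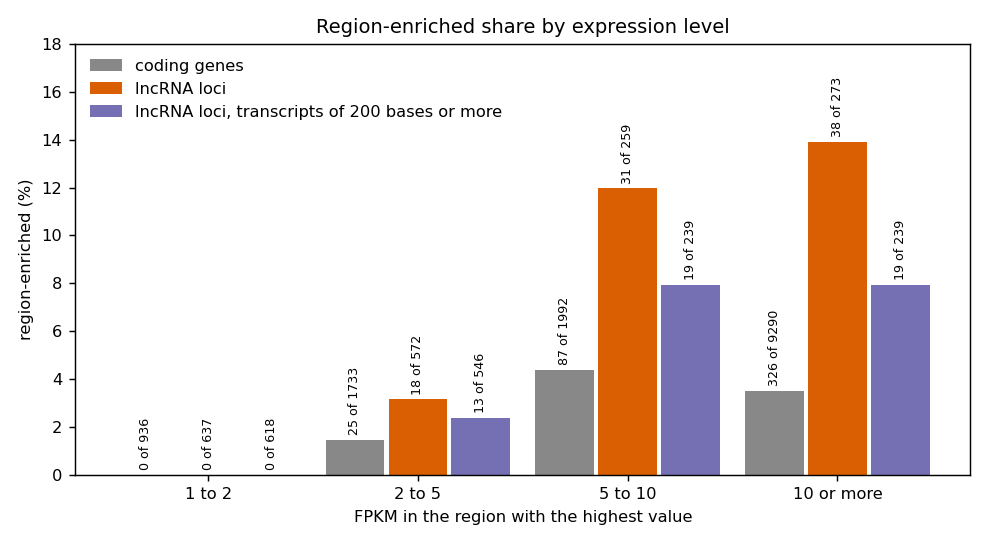
Percentage of lncRNA loci and of coding genes enriched in 1 region, in bins of the highest FPKM over the 4 regions. In the top bin the share was 13.9% of 273 lncRNA loci, 7.95% of 239 when only transcripts of 200 bases or more were used, and 3.51% of 9290 coding genes.

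Among lncRNA loci higher in the SVZ than in STR, XLOC_006027, next to the neuroblast gene Sox4 at chromosome 13, 29034917 to 29045551, was at 17.5 and 26.0 against 2.08 FPKM (2.86 ± 0.47). XLOC_014951, XLOC_007286 and XLOC_010367 were 2.87 ± 0.57, 2.48 ± 0.31 and 2.82 ± 0.35 higher, and the first pair was listed at 0 in STR. XLOC_004581, next to the striatal gene Ppp1r1b at chromosome 11, 98210052 to 98219597, followed the striatal pattern, at 24.4 and 27.5 FPKM in the SVZ, 30.4 in STR, 0.396 in OB and 0 in DG. XLOC_011758 was at 433 and 453 FPKM in SVZ sample 2 and STR and at 0.108, 0.367 and 0.0662 in SVZ sample 1, OB and DG, so its difference followed the library sets. XLOC_017510 and XLOC_011757 had the same split. In OB the highest enriched locus was XLOC_004992, at 232 FPKM, a model of 102 bases.

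The levels of named lncRNAs are given here by region, with those that passed limma adjusted over the list alone at the end. Dlx1as, the antisense neighbour of Dlx1 at chromosome 2, 71291395 to 71375962, was at 22.3 and 19 FPKM in the SVZ, 27.7 in OB, 11 in DG and 3.19 in STR (2.37 ± 0.40 for SVZ against STR). Its reads cannot be told apart from those of Dlx1 where the genes overlap. Six3os1, beside Six3 at chromosome 17, 85999991 to 86017736, was at 13.5 and 10.2 FPKM in the SVZ and 9.57 in STR but 0.0594 in OB (3.59 ± 0.41 for SVZ against OB). Dlx6os1, transcribed at the Dlx5 and Dlx6 locus, was at 24.6 and 42.4 FPKM in the SVZ, 33.9 in OB, 18.3 in STR and 2.71 in DG. Miat was highest in DG, at 168 FPKM against 14.1 in STR (3.48 ± 0.59), and Airn in OB, at 9.56 against 0.289 FPKM (3.03 ± 0.32). Sox2ot, which contains Sox2, was at 27.9 and 24.3 FPKM in the SVZ and 5.72 in DG (2.01 ± 0.39). The nuclear RNA Malat1 was at 2311 FPKM in STR and 746 to 1252 in the other libraries, and the imprinted RNA Meg3 at 549 in DG and 910 to 1641 elsewhere. Adjusted over the list alone, 3 of 16 passed limma for OB against STR (Dlx1as, Six3os1 and Airn), 4 of 15 for SVZ against DG (Six3os1, Dlx6os1, Miat and Sox2ot), 2 of 16 for SVZ against OB (Six3os1 and Airn) and 1 of 15 for OB against DG (Airn). For SVZ against STR 0 of 15 passed, where 1 had an unadjusted p under 0.05, and for DG against STR 0 of 15, where 4 did and the smallest adjusted p was 0.0704.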

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

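The bridged values, the values for transcripts of 200 bases or more and those without genes at least 1 log2 unit apart between the SVZ samples were chosen after seeing the data. Counts here are of genes of all kinds, given as higher and lower in the first region named. The causes of the changes were not tested, except where the setting itself moves a count by construction, as the pseudocount, the size threshold and the detection limit do. No paired analysis was possible because only the SVZ samples carry replicate numbers. Without either SVZ sample limma could not be run, since no residual degree of freedom was left. Read depth is unknown, so its effect on low genes was not measured.

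With a pseudocount of 0.1 the counts by size were 608 and 123 for SVZ against STR, 1619 and 685 for OB against STR, 968 and 929 for DG against STR, 819 and 974 for SVZ against OB, 1211 and 617 for SVZ against DG, and 1161 and 461 for OB against DG. In the same order a pseudocount of 5 gave 28 and 12, 315 and 176, 218 and 193, 98 and 188, 130 and 165, and 174 and 118. A difference of at least 1 gave 1031 and 249, 4320 and 1232, 2535 and 1511, 1250 and 2218, 1847 and 1288, and 2203 and 903. For OB against STR, where 909 were higher and 368 lower as deposited, median ratio scaling gave 491 and 567 and upper quartile scaling 498 and 557. Without genes 1 apart between the SVZ samples, SVZ against STR had 132 and 10, and the lower counts were 214 for OB and 254 for DG against STR. Bridged through the SVZ, the higher counts were 439 for OB and 298 for DG against STR. limma made calls under 2 of the settings: at a minimum of 5 FPKM it called 6 for DG against STR, 68 for SVZ against OB, 67 for SVZ against DG and 22 for OB against DG, and with transcripts of 200 bases or more 60 for SVZ against OB.

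For region-enriched genes, highest and lowest, a pseudocount of 0.1 gave 270 and 10 for the SVZ, 481 and 81 for OB, 249 and 388 for DG, and 91 and 66 for STR. In the same order a pseudocount of 5 gave 6 and 0, 89 and 15, 63 and 18, and 9 and 1, and a difference of at least 1 gave 357 and 22, 1047 and 169, 516 and 365, and 179 and 237. With the transcript of highest mean the lowest counts were 101 for DG and 81 for STR. Without genes 1 apart, 1 gene was lowest in the SVZ, 5 were highest and 4 lowest in STR, and bridged values gave 7 and 2 for STR.

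Leaving out either SVZ sample moved the counts for SVZ against STR to 130 to 393 higher (130 without sample 1) and 16 to 138 lower, and the lower count for SVZ against OB to 405 to 822. Genes highest in the SVZ numbered 47 to 147 and lowest 4 to 5, and genes highest in STR 6 to 109 and lowest 6 to 43. Detected lncRNA loci numbered 3090, 2843, 1799 and 2896 in SVZ, OB, DG and STR at 0.1 FPKM, and 317, 280, 290 and 314 at 5 FPKM. The excess of enriched lncRNA loci over coding genes, 3.32 points, was 1.5 in bins of the mean value, 6.70 with a pseudocount of 0.1 and 1.48 for transcripts of 200 bases or more.

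The relative median of ribosomal protein genes changed sign, to 0.21 for SVZ against STR without SVZ sample 1 (range -0.96 to 0.21 over both omissions), and bridged to 0.0606 for OB and 0.0785 for DG against STR. Bridging also turned Mtrnr2l in both comparisons (0.32 in each), XLOC_011758 (0.24), XLOC_011757 (0.17) and XLOC_007863 (0.21) in OB against STR, and XLOC_017510 (0.39) in DG against STR. XLOC_022764 in SVZ against STR turned to 0.61 with transcripts of 200 bases or more. Of 2579 further values of single genes and lists, 1827 kept their direction within the spread and 742 moved. The counts of catalogue transcripts and loci stayed within 1.5 times under both joining and length settings, and 64 to 65 of the 126 list medians lay outside the central range of random lists when an SVZ sample was left out.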

Other observations

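The tests for the library sets, for more striatal tissue in SVZ sample 2 and for striatal tissue in the SVZ dissection were chosen after the results were seen. The tests of GC content, pseudogenes and neighbouring genes were not.

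Some genes parted the regions outside the lists, and those named here were chosen after their values were seen. Some were higher in both SVZ samples than in STR: the thyroid hormone-binding protein gene Crym was at 517 and 210 FPKM in the SVZ samples and 82.5 in STR, the neuropeptide gene Nts at 46.4 and 39.3 against 6.83, and Pdyn at 133 and 116 against 31.2. The homeobox genes Meis2 and Pbx3 set DG apart from all other regions: Meis2 was at 171, 143, 207 and 135 FPKM and Pbx3 at 30.5, 28.3, 101 and 31.5 FPKM in SVZ samples 1 and 2, OB and STR, against 1.35 and 1.29 FPKM in DG. Six3, also a homeobox gene, was at 42.7, 35.7 and 31 FPKM in the SVZ samples and STR, 0.210 in OB and listed at 0 in DG. Grm2, a metabotropic glutamate receptor gene, was at 103 FPKM in OB and 118 in DG, against 0.866, 0.480 and 0.312 in the SVZ samples and STR.

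SVZ sample 2 correlated more with STR than with SVZ sample 1 across coding genes. Whether sample 2 held more striatal tissue could not be decided. Relative to all coding genes, striatal projection neuron genes were 0.1366 log2 units higher in sample 2 than in sample 1. The range leaving out each gene was 0.124 to 0.150, below the mark of 0.5, which was chosen after the results were seen. The median of these genes in sample 1 was already 113% of the STR value, so more striatal tissue had little room to raise them. Libraries made or processed in 2 sets may explain the correlation: short RefSeq transcripts were detected at least 6.375 times as often in SVZ sample 2 and STR as in any of the other 3 libraries. Removing the GC trend cut the gap in r from 0.0248 to 0.004525, so whether GC content carries the whole gap cannot be told apart from other set differences, because a small gap remained. No biological explanation was tested, and the sets share 1 region only, the SVZ.

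Between the SVZ samples 112 coding genes lay at least 2 log2 units apart, 32 higher in sample 1 and 80 in sample 2, of which 32 were ribosomal protein genes. Reads shared with processed pseudogenes, counted differently in the sets, are a candidate explanation. The direction was mixed. Of the 75 genes with a sequence that were higher in sample 2, 56 had a copy. Gapdh, with 167 copies, was lower in sample 2. Of the 106 genes with a sequence 60.4% had such a copy, 5.773 times the 10.5% of other genes in the same expression bins. Fisher's exact test compared them with all other coding genes, without matching of expression (odds ratio 15.3, p = 9.0e-39). Of all 13898 coding genes with a sequence, 9.46% had a copy. GC content may contribute too, since the genes higher in sample 1 had a median GC 10.52 percentage points above those higher in sample 2 (58.8% of 31 genes and 48.3% of 75). Across the sets, 57 of 261 genes lower in OB than in STR and 70 of 311 lower in DG had a copy. Over both directions the shares were 7.18% of 1114 genes for OB and 11.1% of 754 for DG, near the 9.46% of all coding genes. Within the sets the counts were 0 of 375 for SVZ sample 1 below OB and 1 of 193 for OB below DG, but 4 of 9, a larger share from few genes, for SVZ sample 2 below STR. Over both directions the shares were 1.98%, 2.21% and 9.16% in the same order. A difference between the animals of the SVZ samples was not tested.

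Striatal projection neuron genes stood near the striatal level in the SVZ. Striatal tissue in the dissection is a candidate explanation. The levels of these genes restate the pattern, so they cannot tell it from expression by cells of the SVZ. Within the library set of SVZ sample 2 and STR, 16 of the 18 genes lay between 52.1% and 111% of the STR value. The median was 76.2%, against 4.38% in OB and 2.88% in DG. Pdyn at 372% and Penk at 139% lay above the STR value, which an even admixture would not give. None of the 18 genes is in another list, and expression by cells of the SVZ itself was not tested and stays open.

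One hypothesis was that lncRNA loci and their nearest coding genes differ together between OB and DG, 2 regions of the same library set. Across 486 pairs over 5 kb apart, Pearson r was 0.1923, above the upper 2.5% point of 1000 shuffles (0.0862), and r was 0.214 in 479 pairs after the GC trend of the coding genes was removed (upper 2.5% point 0.0910). It was 0.489 for 302 pairs up to 5 kb apart, 0.233 for 271 pairs from 5 to 50 kb and 0.170 for 215 pairs beyond 50 kb, where the upper 2.5% point was 0.132. The relation is across pairs of genes in 2 libraries, and unannotated extensions of the coding transcripts may account for part of it at short distances.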
